A study of Homo sapiens with 6 samples.

How the data were processed

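The series compared HEY human ovarian carcinoma cells transfected with a miR-205 precursor (30 nM, 3 samples) with cells transfected with a negative control precursor (3 samples). Per the labels' protocols, transfection used Lipofectamine and total RNA was isolated after 48 h. Per the labels' protocols, cDNA was amplified with a 3' amplification kit, labelled with biotin and hybridised to Affymetrix U133 Plus 2 arrays. Amplification from the 3' end makes the signal of a probe set depend on its distance from the end of the transcript. The deposited values are GCRMA signals on the log2 scale, and per the series' design text the authors took present and absent calls from MAS5. The submitters' processing notes also name Affymetrix Expression Console, and no versions are given in the sources used here. By its design GCRMA corrects the background by probe sequence, makes the distributions of the arrays alike and summarises the probes of a set. A shift that most genes share is therefore partly removed before deposit. Per the labels, the control arrays were analysed together with the miR-205 arrays; the full set of arrays normalised together is not stated. The upper quartiles of the 6 arrays were 5.187, 5.241 and 5.271 (miR-205) and 5.048, 5.055 and 5.225 (control).

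Of 54675 probe sets, 41097 had a single gene symbol in the platform annotation, 1801 had several and 11777 are unnamed here. The manufacturer's 62 controls are counted among these. Through Entrez identifiers, 41043 of the single-symbol probe sets matched the RefSeq gene table of assembly GRCh38.p14, and none of their symbols changed, while 54 kept the platform's symbol. The 6 manufacturer's controls with a single symbol were left out of the gene table and reported by group. Each of 19775 genes was represented by its probe set with the highest mean over the 6 arrays, chosen without regard to group. Genes were tested where that probe set was at or above 4 on the log2 scale in at least 3 of the 6 arrays, in place of the detection calls, which were not used here. This left 9138 genes. No coordinates are given, since the values name no genome build.

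Groups were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, group as the sole term, two-sided) and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. At least 2-fold means a log2 change of at least 1 in size. Where a group mean lay below 4, the change is given as a bound against 4. Control probe sets were compared with two-sided exact permutation tests. The same code was tested on simulated data of 9138 genes with 3 arrays per group and the error of this comparison. In it 200 genes were changed. It recovered 7.46% of genes changed by 0.5 on the log2 scale, 71.6% of those changed by 1 and 100% of those changed by 2. Of 126 called genes, 7 were unchanged ones. In the real comparison 5924 genes passed, and the adjusted threshold depends on that number. The recovery therefore checks the code and does not give the sensitivity of the real comparison.

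Before the data were examined, 20 gene lists from textbook knowledge were fixed, together with the tests, the alternatives and the rule for naming genes. Of their 548 distinct genes, 48 have no probe set named for them alone in the annotation used and are not reported. The lists are published miR-205 targets, epithelial, mesenchymal, S-phase, G2/M, interferon-stimulated, cholesterol, unfolded protein and amino acid stress, p53 target, TGF-beta response, hypoxia and glycolysis, NF-kB and inflammatory, ErbB and PI3K pathway, cell adhesion and actin, microRNA machinery, cytosolic ribosomal, oxidative phosphorylation, and lysosome and autophagy genes, and leukocyte and endothelial markers. Lists with at least 5 measured genes (18 lists) were tested with camera at its preset correlation of 0.01, adjusted over the lists. Of the 3 lists past the threshold none held with an estimated correlation. There 1 list, the published miR-205 targets, had an unadjusted p below 0.05. With an estimated correlation camera rests on the 4 residual degrees of freedom, so a lost call can reflect low power. By fry 13 lists were called. The fry p tests whether the genes of a list move on balance in a single direction, not whether they differ from other genes. Named genes were the 12 largest falls and 12 largest rises among genes past the threshold with separate groups and a higher group mean of at least 6, ranked by measured log2 changes, including signals below 4. Every measured published target and up to 4 members of each other list with the smallest p were named too, 113 genes in all. Symbols of unnamed loci or clones would have been replaced by the next gene.

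The alternatives fixed in advance were the replicate number as a block, no filter and a filter at 6, renewed quantile normalization, centring on the median, other ways to take a single value per gene, other variance models, and each array left out in turn. Agreement among all probe sets of a gene and changes at their bounds were added after seeing the data. Comparing miR-205 seed matches in 3' untranslated regions was planned and not run, because transcript sequences were not used here. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.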

Results

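Messenger RNA was profiled in HEY cells, an established human ovarian carcinoma line, 48 h after transfection with a precursor of the microRNA miR-205. The microRNA precursor was used at 30 nM in 3 samples, and 3 control samples received a negative control precursor whose dose was not given in the sources used here. Each sample was hybridised to its own Affymetrix U133 Plus 2 array, and the deposited values were GCRMA signals on the log2 scale. The percentage of probe sets at or above 4 on that scale was 30.7, 30.9 and 31 in the miR-205 arrays and 30, 29.9 and 31 in the control arrays. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 3 arrays per group, the number of arrays limits the precision. The mature microRNA was not measured by these probe sets.

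The comparison addressed which messenger RNAs differ between HEY cells given miR-205 and cells given the control precursor, and whether targets of the microRNA are among those that are lower. Transcripts for MYC, a transcription factor that drives cell growth, for the splicing factor HNRNPL and for the chemokine CXCL8 were the 3 that fell most under the naming rule. Transcripts for PSMC3, an ATPase subunit of the proteasome, and for GIT1, a GTPase-activating protein for ARF proteins, rose most. Of 9138 genes tested, 2131 were lower and 3793 were higher in the miR-205 cells at a limma adjusted p below 0.05. By their measured values, 1216 of the lower and 2167 of the higher genes changed at least 2-fold, and 3214 genes did not pass. With changes against a group mean below 4 taken as bounds, these were 1159 and 1926. The 3 miR-205 arrays lay wholly above or below the 3 control arrays for 6633 genes, or 72.6%, where chance gives 10%.

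Control probe sets differed between the groups on the same arrays. The probe set at the 5' end of GAPDH read 11.03 ± 0.50 (SD, n = 3) in the miR-205 arrays and 3.94 ± 0.79 (SD, n = 3) in the control arrays. The middle GAPDH probe set read 12.32 ± 0.22 against 9.02 ± 1.00, while the 3' probe set read 13.33 ± 0.07 against 12.98 ± 0.23 (SD, n = 3 each). Where a group mean lay below 4, the difference is a bound against 4, because detection calls were not used here, so GAPDH 5' was at least 7.03 higher in the miR-205 arrays. For ACTB, the 5' probe set read 4.43 ± 0.56 against 2.82 ± 0.25 (SD, n = 3 each), at least 0.43 higher, and the 3' probe set differed by -0.50 on the log2 scale. The middle ACTB probe set differed by -1.06, with overlapping arrays (two-sided exact permutation p = 0.3). The probe set for 18S ribosomal RNA read 6.56 ± 0.86 in the miR-205 arrays against 10.6 ± 0.43 in the control arrays (SD, n = 3 each). The bioB hybridisation spike, added to every sample at a fixed amount, read 10.35 ± 0.39 against 11.84 ± 0.56 (SD, n = 3 each). The other spikes, bioC, bioD and cre, differed by less, at -1.19, -0.44 and -0.09 on the log2 scale. For all of these except the middle ACTB probe set the 2 groups did not overlap, with a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. No scan date or labelling batch was given, so a batch and the treatment cannot be told apart.

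**Figure D1:**
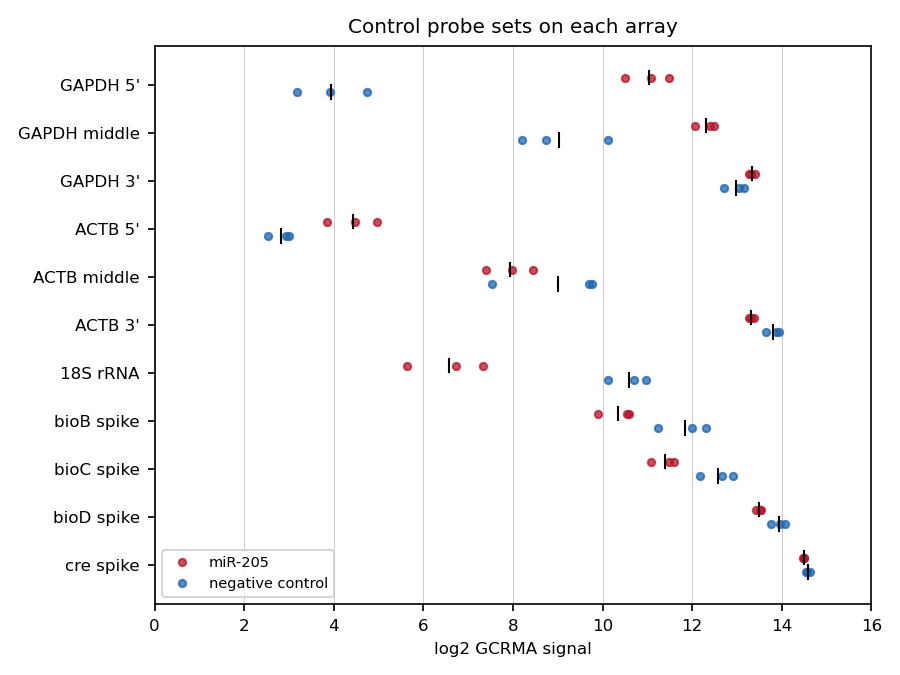
Log2 GCRMA signal of control probe sets (horizontal axis), with a point for each of the 3 miR-205 arrays (red) and 3 negative control arrays (blue) and a bar at each group mean. The GAPDH 5' points average 11.03 in the miR-205 arrays and 3.94 in the control arrays, while the GAPDH 3' points average 13.33 and 12.98.

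Probe sets of the same gene often changed by different amounts. Among 2268 genes with at least 2 probe sets at a mean of 6 or more, the correlation across genes of their log2 changes was 0.393, and genes are not independent replicates. Simulations with a single change per gene and the measured error gave 0.9353 to 0.9441. Of 858 such pairs in which both probe sets passed the threshold, 23.9% were called in opposite directions, where 49.7% would be opposite without any link. Among 3896 genes with at least 2 probe sets past the filter, 376 were lower and 670 higher at every such probe set, and 660 held calls in both directions. By the brightest probe set alone, 998 of these genes were lower and 1394 higher. Where the probe sets of a named gene past the filter did not all pass in the same direction, this is given beside the gene.

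**Figure D2:**
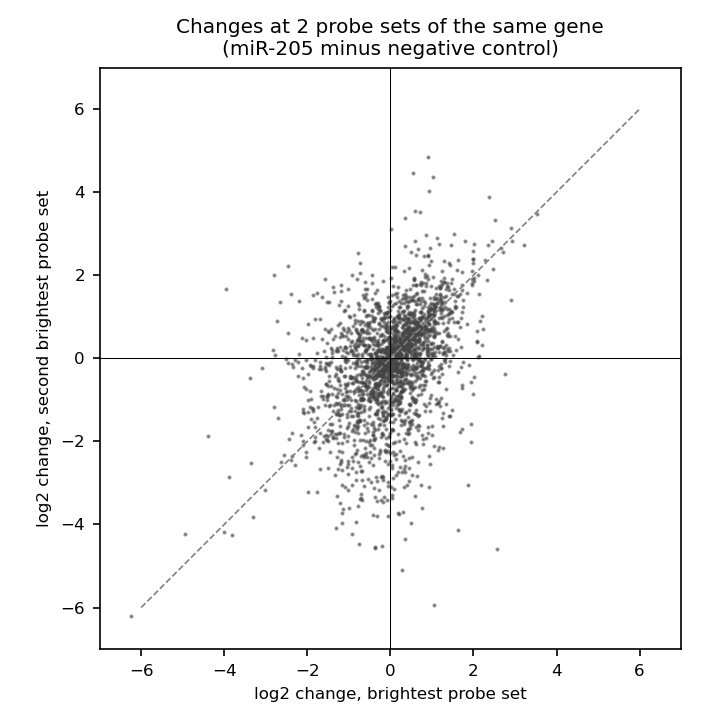
Log2 change (miR-205 minus negative control) at the brightest probe set of a gene (horizontal axis) and at its second brightest (vertical axis), as measured, with a point for each of 2268 genes and a dashed line of equality. The points scatter widely around the line, with a correlation of 0.393.

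The 12 largest falls and rises were ranked by measured values, and with changes at their bounds 10 of each remained, without LMO7, EEIG2, CDC37 and MORN4. Among the genes that fell most, MYC read 3.68 ± 0.78 in the miR-205 arrays and 11.02 ± 0.37 in the control arrays (SD, n = 3 each; limma adjusted p = 4.2e-05). With the group mean below 4 taken as a bound, MYC fell by at least 7.02 on the log2 scale. HNRNPL fell by at least 5.73, and both of its probe sets were lower. CXCL8, which encodes interleukin-8, fell by 5.56 ± 0.26 (SE), from 10.81 to 5.25. SNRNP40, a component of the U5 small nuclear ribonucleoprotein, fell by at least 4.57. MYC, CXCL8 and SNRNP40 each had a single probe set past the filter, so agreement between probe sets could not be read for them. Another CXCL8 probe set lay below 4 on every array. The tetraspanin CD9 fell by 4.95 ± 0.29 (SE) at its single probe set past the filter. ALYREF, an mRNA export factor, fell by 4.43 ± 0.34 (SE), with both probe sets lower. LMO7 and EEIG2, each with a single such probe set, fell by at least 3.10 and 3.32. The remaining 4 of the 12 had probe sets that did not all pass. TRIO fell by 4.94 at its brightest probe set, 3 of 4 were lower, and the fourth differed by 0.60 without passing. ELAVL1, an RNA-binding protein that stabilises messenger RNAs, fell by 4.42 ± 0.39 (SE) and was lower at 2 of 3 probe sets. TLNRD1 fell by 4.67 and the kinase gene CDC42BPA fell by 4.42, while the other probe set of each differed by -0.13 and -0.29 without passing.

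The genes that rose most were PSMC3 and GIT1. PSMC3 read 9.09 ± 0.14 in the miR-205 arrays and 2.99 ± 1.5 in the control arrays (SD, n = 3 each; limma adjusted p = 0.000234), a rise of at least 5.09. GIT1 rose by 4.97 ± 0.20 (SE), from 4.54 to 9.51. POLM, a DNA polymerase of end joining, rose by at least 3.35. SCEL, a precursor protein of the cornified envelope, rose by at least 3.43 and was higher at both probe sets. The endosomal sorting gene HGS rose by at least 3.85, the HSP90 co-chaperone CDC37 by at least 2.14, the transcription factor FOXH1 by at least 3.63 and MORN4 by at least 2.52. APEH, an acylpeptide hydrolase, rose by 3.78, SPECC1L by 3.57, the lysosomal acid phosphatase ACP2 by 3.55 and the xylosyltransferase XYLT2 by 3.52, the last at both of its probe sets. SCEL and XYLT2 were the only genes of these 12 with more than 1 probe set past the filter. The GAPDH 5' control was at least 7.03 higher in the miR-205 arrays, in the direction of the rises.

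**Figure D3:**
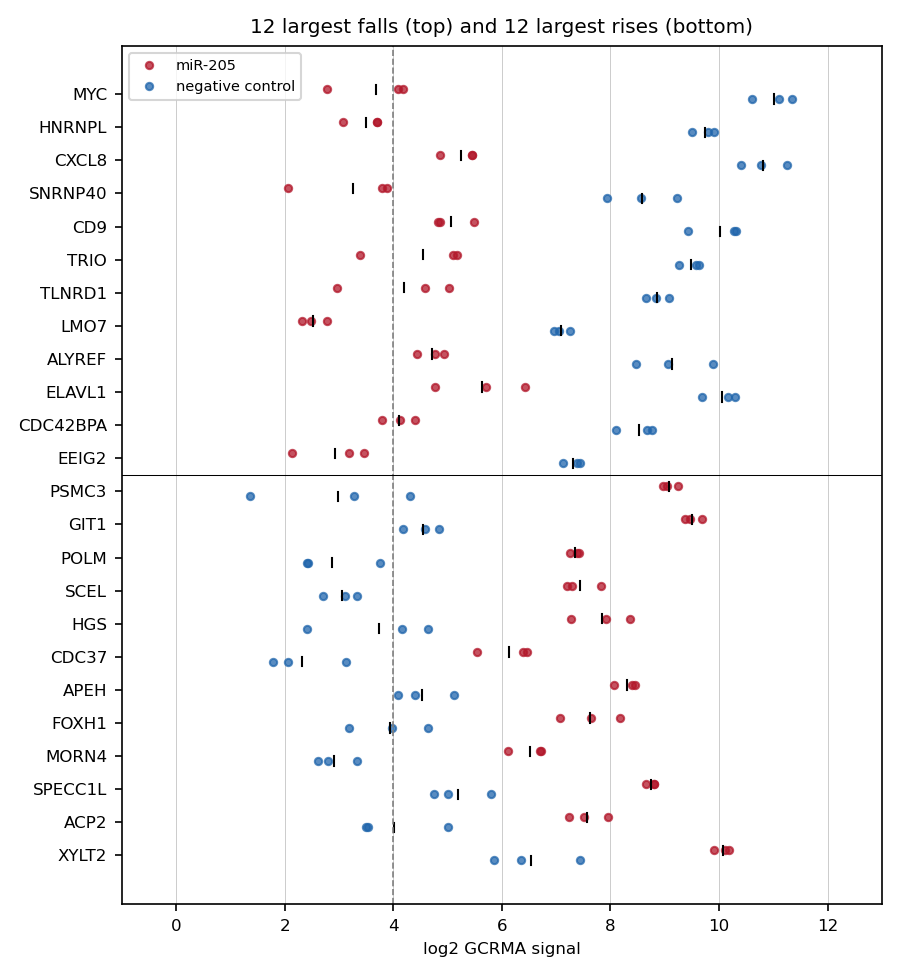
Log2 GCRMA signal (horizontal axis) of the 12 genes with the largest fall and the 12 with the largest rise by measured values, with a point for each of the 3 miR-205 arrays (red) and 3 negative control arrays (blue), a bar at each group mean and a dashed line at 4. In all 24 genes the groups are separate, and MYC averages 3.68 in the miR-205 arrays against 11.02 in the control arrays.

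Genes published as targets of miR-205 were lower as a list. Of 21 measured targets, 10 fell, 6 rose and 5 did not pass, and the counts adjusted over the list alone were the same. The median log2 change of the list was -0.48, against 0.27 for all tested genes (camera adjusted p = 0.0336). The call was lost with an estimated correlation (adjusted p = 0.64) and without negative control replicate 1 (adjusted p = 0.0531). ZEB1, a repressor of epithelial genes and one of the best-known miR-205 targets, fell by 1.22 ± 0.19 (SE) and at both probe sets. HMGB3 fell by 3.79 ± 0.36 (SE) at the brightest of its 2 lower probe sets, and the Mediator subunit MED1 fell by 2.11 ± 0.21 (SE), with all 4 probe sets lower. NOTCH2 fell by 1.08 ± 0.16 (SE), with all 3 probe sets lower. RUNX2, E2F5 and ZEB2 each had a single probe set past the filter and fell by 1.47, 0.77 and 0.53. YAP1 fell by 1.98 at its brightest probe set and was lower at 1 of 3. SMAD1 fell by 1.87 at its brightest probe set and was 1.53 higher at the other, and CREB1 fell by 1.32 with 2 probe sets lower and 2 higher out of 7.

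The targets that rose were CLDN11, by at least 1.15, the integrin ITGA5 by 1.23, VEGFA by 0.95, BCL6 by 0.65, SMAD4 by 0.61 and ACSL1 by 0.57. A second probe set of SMAD4 fell by at least 1.67, and that of ACSL1 read 3.86 in the miR-205 arrays against 4.48 in the control arrays without passing. Calls ended when single arrays were left out for ACSL1 (adjusted p up to 0.139, without negative control replicate 3), ZEB2 (up to 0.0913, without miR-205 replicate 2), BCL6 (up to 0.0722, without miR-205 replicate 1) and SMAD4 (up to 0.0601, without negative control replicate 3). YES1, PRKCE, PHC2, E2F1 and DDX5 did not pass, with log2 changes of -0.36, -0.48, -0.41, -0.30 and -0.12 at their brightest probe sets. A second probe set of PRKCE fell by at least 3.23 and that of YES1 fell by 0.70, while neither of the 2 for E2F1 passed. PHC2 passed without negative control replicate 2 (adjusted p = 0.0235), and its other probe set was at least 2.02 higher. Of the 13 targets with at least 2 probe sets past the filter, 4 were lower at every one, none was higher at every one, and 3 held opposite calls. The GAPDH 5' probe set was at least 7.03 higher on the miR-205 arrays compared. The study's comparison of predicted targets was not analysed here.

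**Figure D4:**
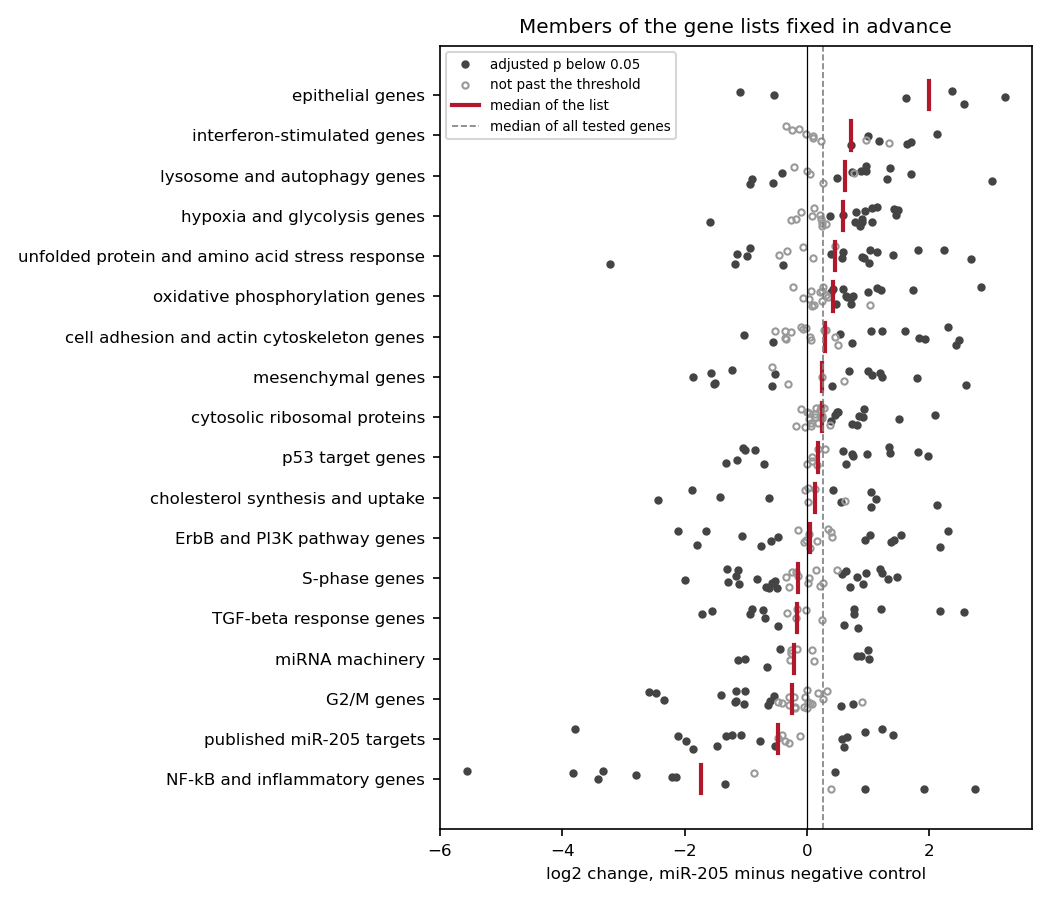
Log2 change (miR-205 minus negative control, horizontal axis) of each measured gene of the 18 tested lists as measured, without bounds, filled where the adjusted p was below 0.05. A red bar marks each list's median and a dashed line the median of all tested genes, 0.27. The lowest median, -1.74, belongs to the NF-kB and inflammatory genes, and the published miR-205 targets have a median of -0.48.

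Inflammatory genes regulated by NF-kB were also lower as a list. Of 14 measured, 8 fell, 4 rose and 2 did not pass, with the same counts adjusted over the list alone and a median of -1.74. Besides CXCL8, the chemokine genes CXCL2 fell by 2.79 ± 0.21 (SE) and CXCL1 fell by 2.21 ± 0.15 (SE), while TNFAIP2 rose by 2.74 ± 0.21 (SE). The camera adjusted p was 0.0336, and with an estimated correlation the call was lost (adjusted p = 0.77). A single gene of the list had more than 1 probe set past the filter. These arrays were the ones on which 18S ribosomal RNA differed by -4.03 and GAPDH 5' was at least 7.03 higher.

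Genes of the G2 and M phases of the cell cycle were lower as a list, with 12 of 32 lower, 2 higher and 18 not passing. Adjusted over the list alone, 11 were lower and 1 was higher, and the median was -0.25 (camera adjusted p = 0.00963). The call was lost with an estimated correlation (adjusted p = 0.77). The mitotic kinesin KIF20A fell by 2.59 ± 0.19 (SE), the ubiquitin-conjugating enzyme UBE2C by 2.33 ± 0.24 (SE), the cytokinesis gene ANLN by 1.40 ± 0.16 (SE) and the topoisomerase TOP2A by 1.17 ± 0.16 (SE), the last at both probe sets. S-phase genes went both ways, with 12 of 33 lower and 10 higher (median -0.15, camera adjusted p = 0.326). Among them PCNA, UHRF1 and CCNE2 fell by 1.31, 1.28 and 2.00, the last at 1 of 2 probe sets, and GINS4 rose by 1.23. The middle GAPDH probe set was 3.30 higher in the miR-205 arrays, opposite to the falls, and a link to these genes was not tested.

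Epithelial and mesenchymal genes were of interest because miR-205 is known for repressing ZEB1 and ZEB2. Most epithelial genes were below the filter, and 6 of 31 with a probe set were measured. Of these 4 rose and 2 fell, with a median of 1.99, or 1.08 with changes at their bounds (camera adjusted p = 0.669). The keratin genes KRT8, KRT7 and KRT18 rose by 2.56 ± 0.40, 2.36 ± 0.38 and 1.62 ± 0.27 (SE), KRT7 at all 3 probe sets. The plakophilin gene PKP3 rose by at least 0.54. The 2 that fell, OCLN and DSP, lay outside the naming rule and fell by 1.10 and 0.53. Of 19 mesenchymal genes, 8 rose and 7 fell (median 0.25, mean 0.06, camera direction down, adjusted p = 0.669). The transcription factor genes SNAI2 and TWIST1 fell by 1.86 ± 0.19 and 1.51 ± 0.17 (SE). The integrin gene ITGA5 rose by 1.23 ± 0.15 (SE). Outside the naming rule, COL6A2, COL1A1 and SPARC were among the 8 that rose. TWIST2 fell by 1.57 at its brightest probe set and was at least 0.80 higher at the other. On the miR-205 arrays the 5' control of GAPDH was at least 7.03 higher and that of ACTB at least 0.43 higher.

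Among genes of energy metabolism, more rose than fell. Of 27 oxidative phosphorylation genes 14 rose and none fell (median 0.43, camera adjusted p = 0.082, and 0.0115 without the filter on dim probe sets, where the list passed). With an estimated correlation it did not pass (adjusted p = 0.77). UQCRC1 rose by at least 2.79, NDUFV1 by 1.73, SDHA by 1.21 and NDUFS3 by 1.00. Of 25 hypoxia and glycolysis genes 14 rose and 1 fell, or 13 and 1 adjusted over the list alone (median 0.59, camera adjusted p = 0.206, and 0.0223 without the filter, where the list passed). This list, too, did not pass with an estimated correlation (adjusted p = 0.77). The hypoxia and glycolysis genes that rose include GAPDH, at 0.90, whose control probe sets differed by their position along the transcript. NDRG1, SLC2A3 and SLC2A1, the last 2 of which encode glucose transporters, rose by 1.48, 1.42 and 1.06, SLC2A3 at 1 of 3 probe sets, and P4HA1 fell by 1.59. Cytosolic ribosomal protein genes numbered 29, of which 11 rose and none fell, or 9 adjusted over the list alone (median 0.24, adjusted p = 0.326). RPL3, RPL8, RPS9 and RPS3 rose by 0.92, 0.85, 0.81 and 0.73. Of 15 interferon-stimulated genes 6 rose and none fell (median 0.72, or 0.52 with changes at their bounds, adjusted p = 0.335). Against 10000 random lists matched on mean level, the measured medians of the hypoxia and glycolysis, oxidative phosphorylation, epithelial and G2/M lists lay at percentiles 99.4, 99, 100 and 1.39, that of the published targets at 0.65 and that of the NF-kB genes at 0. The other tested lists lay between 5.41 and 97.3. The epithelial percentile rests on 6 genes, with PKP3 at its measured change of 3.24. With PKP3 at its bound of 0.54 the epithelial median was 1.08, within the central range of the random medians, -0.73 to 1.15. The interferon-stimulated genes that rose included IFIT3 and IRF7, which rose by 2.13 and 1.71, HERC6, which rose by 1.00, and IFIT1, which rose by at least 0.52. The ACTB 5' probe set was at least 0.43 and the GAPDH 5' probe set at least 7.03 higher on the miR-205 arrays.

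Stress and signalling lists held genes that moved in both directions. Of 23 genes of the unfolded protein and amino acid stress response 12 rose and 6 fell, or 13 and 7 adjusted over the list alone (median 0.46, camera adjusted p = 0.939). ASNS and SLC3A2, of amino acid supply, rose by 1.82 and 2.68, and CEBPB and the chaperone gene HSP90B1 fell by 3.21 and 1.18. Of 21 p53 target genes 9 rose and 6 fell (median 0.18, adjusted p = 0.939), with POLH, TP53I3 and DDB2 up by 1.97, 1.81 and 1.35, and RRM2B, which fell by 1.33. In the ErbB and PI3K pathway list 7 of 23 rose and 7 fell (median 0.05, adjusted p = 0.829). MTOR rose by 2.30 and TSC2 by at least 0.93, while RHEB, at all 5 probe sets, and RICTOR, at both, fell by 2.11 and 1.80. Cholesterol genes split into 6 higher and 4 lower of 15 (median 0.13, adjusted p = 0.899), with SQLE and INSIG1 falling by 2.44 and 1.87, the latter at 2 of 3 probe sets, and FDPS and HSD17B7 rising by 1.05 each. For the cholesterol and ErbB lists the camera direction was down although the medians lay above 0. Of 19 TGF-beta response genes 7 rose and 7 fell (median -0.17, mean 0.08, adjusted p = 0.691). COL4A2 rose by 2.17 and BHLHE40 fell by 1.72, while THBS1 and LTBP2 rose by 2.56 and 1.21 at their brightest probe sets and were lower at others, by up to -4.59 and -1.72. These genes were read on arrays whose GAPDH 5' signal was at least 7.03 higher in the miR-205 group.

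Of 26 cell adhesion and actin genes 10 rose and 2 fell (median 0.30, camera adjusted p = 0.743). TPM2, TLN1, CNN2 and ITGA5 rose by 2.43, 1.92, 1.60 and 1.23. Of 18 lysosome and autophagy genes 9 rose and 4 fell (median 0.61, adjusted p = 0.691). HEXA, GLA and WIPI1 rose by 3.02, 1.71 and 1.31, while ATG12 rose by 1.35 at its brightest probe set and was lower, at -1.09, at another. Of 14 genes of the microRNA machinery 4 rose and 4 fell (median -0.21, adjusted p = 0.527), with DROSHA and TARBP2 up by 1.00 and 0.81. DCP2 and TNRC6A held opposite calls, with DCP2 at -1.02 and TNRC6A at 0.88 by their brightest probe sets. For the lists from the epithelial genes to the microRNA machinery, unless given, the counts adjusted over the list alone equalled those over all genes. None of 13 leukocyte markers with a probe set passed the filter. Of 11 endothelial markers 3 did, and TIE1 and ROBO4 rose by 2.83 and 1.35 while CDH5 differed by -0.21 without passing (adjusted p = 0.544). GAPDH 5' was at least 7.03 higher on the miR-205 arrays, and 18S ribosomal RNA differed by -4.03.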

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

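The camera alternatives with an array left out, a replicate block, no filter or an estimated correlation were planned, and the other tests in this part were chosen after the results they bear on were seen. The bioB, bioC, bioD and cre spikes differed by -1.50, -1.19, -0.44 and -0.09 on the log2 scale. Control probe sets, outside the gene comparison, differed in both directions, with 18S ribosomal RNA at -4.03. Of those higher in the miR-205 arrays, the measured group means differed by 7.09 at GAPDH 5', 3.30 at GAPDH middle and 1.61 at ACTB 5' on the log2 scale. Since the control means of both 5' probe sets lay below 4, the rises there are bounds of at least 7.03 and 0.43. The groups did not overlap at any of these 3. Of 2164 probe sets past the filter that are unnamed here or match several genes, 819 were higher in the miR-205 cells and 581 lower by limma at an adjusted p below 0.05.

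The first pattern is that 5924 of 9138 genes differed between the groups. A change of whole transcripts as the only cause is argued against by pairs of probe sets of the same gene, 23.9% of which were called in opposite directions where both passed, against a bound of 2.5% set for that explanation. Uneven coverage along transcripts between the groups needs probe sets of a gene to change by different amounts. Their correlation was 0.393, against 0.9353 to 0.9441 in simulations with 1 change per gene and array error alone. Any other cause of disagreement between probe sets would lower it too. The value therefore does not single out uneven coverage. At the control probe sets coverage did differ. GAPDH 5' minus 3' was -2.30 in the miR-205 arrays and -9.04 in the control arrays, and ACTB -8.89 and -10.99, without overlap. The 5' means of the control arrays lay below 4, so these gaps include signal near background. The middle ACTB probe set went the other way, at -1.06, with overlapping arrays. Uneven coverage may account for part of the calls. The 6 arrays allow 10 splits, too few for a share under 0.05. Only the real split, 1 of 10, gave as many as 5924 genes. The highest other split gave 0 by limma (85 at an unadjusted p below 0.05). Every other split mixes miR-205 and control arrays in both groups, so the group difference enters its error. Few calls there were fixed in advance and are no support for the real split. The bioB, bioC and bioD spikes, which are not RNA of the cells, differed by -1.50, -1.19 and -0.44 between the groups without overlap. The groups thus differed also in the normalised signal of RNA that did not come from the cells. Since normalisation makes the arrays alike, a difference in the RNA of the cells could also shift the spikes. Signal before normalisation was not examined. Real responses to miR-205 stay open beside a difference in RNA, amplification or hybridisation, since their shares of the calls cannot be told apart in these 6 arrays.

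The second pattern is that published miR-205 targets were lower as a list. A shift of all genes of like level is argued against by the list's median, at percentile 0.65 of 10000 random lists matched on level. With genes at the mean of 2 or more probe sets the camera adjusted p was 0.0361, so the call did not need the brightest alone. That mean still contains the brightest probe set, so an effect of its choice stays open in part. The list's adjusted p ranged from 0.026 to 0.64 over the camera alternatives, and was 0.0531 without negative control replicate 1. Lowering of its targets by miR-205 stays open and was not tested apart from the list itself, since seed matches were not analysed here. Uneven coverage stays open, since 23.1% of the 13 targets with several probe sets held opposite calls, against 16.9% of all such genes, and coverage followed the groups.

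The third pattern is that NF-kB and inflammatory genes were lower as a list, a call lost with an estimated correlation (adjusted p = 0.77; 0.026 to 0.0404 over the other camera alternatives). A shift of all genes of like level is argued against by a median at percentile 0 of the 10000 matched random lists. A weaker interferon response to the transfected RNA, as large as this fall, is argued against by the interferon-stimulated genes, whose median of 0.715 lay 2.18 above that of the list after the level-matched medians were removed (SD of the interferon-stimulated genes 0.79); a smaller one stays open, with their median at percentile 62.6 of matched random lists. Uneven coverage along transcripts cannot be told apart from a treatment effect here, because agreement between probe sets can be read for 1 gene of the list only. An effect of miR-205 on these genes stays open and untested.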

How the results depend on the processing

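Agreement among probe sets, the mean of 2 or more probe sets and changes at their bounds were chosen after seeing the data; the other alternatives were planned, and those on seed matches were not run. The numbers of genes lower, higher and at least 2-fold changed stayed within 1.5 times under another filter, normalization, variance model or single arrays left out, with 5142 to 5603 calls in all in the last. The mean of all probe sets gave 1359 genes at least 2-fold higher. Tests of every probe set, which count more features, gave 4730 lower and 6506 higher, 3202 and 3955 of them at least 2-fold. Requiring all probe sets of a gene to agree, among fewer genes, gave 376 lower and 670 higher, 188 and 327 at least 2-fold. With changes at their bounds 1159 and 1926 genes were at least 2-fold lower and higher. Centring moved the median change from 0.27 to 0.12 and the higher share of calls from 64.0% to 56.3%. The replicate numbers did not pair the arrays (correlations of deviations 0.275, 0.229 and -0.292); a replicate block gave 5858 calls, 5686 of them shared, and an adjusted p of 0.026 for the published targets. Lists past the threshold numbered 5 without the filter, 0 with an estimated correlation and 13 by fry, against 3. For published targets the adjusted p was 0.0266 to 0.0531 with each array left out, the highest without negative control replicate 1, and 0.64 with an estimated correlation. For TGF-beta response genes fry gave the opposite direction (adjusted p = 0.0289). The least favourable probe set reversed 13 of the 41 named genes with 2 or more past the filter, at 0.60 for TRIO, 0.22 for ELAVL1, 1.04 for CREB1, 1.53 for SMAD1, -2.89 for SMAD4, -0.62 for ACSL1, 2.83 for PHC2, 0.89 for TWIST2, -4.59 for THBS1, -1.72 for LTBP2, 1.27 for DCP2, -2.57 for TNRC6A and -1.09 for ATG12. For SMAD4, ACSL1, PHC2 and TWIST2 a group mean at that probe set lay below 4, and the bounds are -1.67, -0.48, 2.02 and 0.80. The mean of all probe sets reversed ACSL1 (-0.026), LTBP2 (-0.25) and TNRC6A (-0.71). The cause was not tested. Of 113 named genes, 90 kept their direction and call under every alternative that gave a value. Signal over background limits 724 called genes whose lower group mean was below 4.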

Other observations

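The tests in this part were chosen after the results were seen. Genes of stratified epithelium were examined as a further group because SCEL and PKP3 rose. Of 32 textbook genes 8 were measured, and 3 rose while 4 fell. The laminin gene LAMB3 rose by 1.88 ± 0.20 (SE), the 14-3-3 gene SFN by 1.21 ± 0.17 (SE) and S100A2 by 0.86 ± 0.29 (SE). The desmosome genes PKP2, DSG2 and DSC2 fell by 1.36 ± 0.30, 0.97 ± 0.20 and 0.62 ± 0.21 (SE), and PERP fell by 0.45 ± 0.14 (SE). A rise of such genes as a group is not shown by camera (p = 0.488, direction down, 0.543 with an estimated correlation), and with 8 genes moving both ways it stays open.

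The subunit genes of the proteasome were examined because PSMC3 rose most. Of 32 measured, 15 were higher and 6 lower. A rise of the whole proteasome by about as much as PSMC3 is argued against by the other subunits, whose median change was 0.23. Their range was from -1.72 to 1.44, against at least 5.09 for PSMC3. Because PSMC3 was picked as the largest rise, smaller changes of the others were likely in advance. A smaller shared rise was not tested. Families of genes that share a symbol stem were tested with camera over 60 families of at least 15 genes, and 0 passed after adjustment, with 2 at an unadjusted p below 0.05.

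The median change of all genes depended on their mean level. By measured values it was 0.85 for the 1201 genes below 5, or 0.52 with the 751 of them that have a group mean below 4 at their bounds. It was 0.47 for the 2331 from 5 to 7, 0.22 for the 2892 from 7 to 9 and 0.07 for the 2714 at 9 and above. Without the filter the median of all 19775 genes was 0.10, against 0.27 for the tested ones. The filter keeps dim genes that are high in 1 group alone, so the median below 5 depends on it. Over all tested genes the first principal component held 86.2% of the variance and separated the groups, with scores of -67.7, -47.2 and -50.4 for the miR-205 arrays and 52, 67.4 and 45.8 for the control arrays. Correlations between arrays were taken across all 54675 probe sets, most of them below 4. They were 0.993 to 0.996 within the miR-205 group, 0.985 to 0.989 within the control group and 0.94 to 0.964 between groups.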
